A study of Mus musculus with 3 samples.

How the data were processed

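Lung cells of control mice and of Kras mutant mice were profiled by Drop-seq in 3 libraries, 2 from pooled control cells and 1 from Kras mutant cells. Per the labels' protocols, mice had 4 doses of tamoxifen, immune cells were depleted with CD45 microbeads, fGFP-positive cells were enriched by FACS in a mode that lets through other cells, and libraries were sequenced on a HiSeq as 150 bp paired ends. Cells of all controls were pooled, and the Kras mutant animals were handled separately. The deposited files hold counts of UMIs per gene and cell barcode, as whole numbers with no normalisation visible. The genome build mm10 and the tool Seurat are named per the submitters' processing notes. The aligner, the counting program and the annotation are not given in the sources used here. Gene positions came from GENCODE mouse release M21.

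Each file held 12000 barcodes. Barcodes were kept with at least 500 UMIs, at least 300 genes and a mitochondrial share under 20%, which left 11356, 10433 and 7080 in Control 1, Control 2 and the Kras mutant library, with median depths of 1019, 1005 and 908 UMIs. The minimum of 500 UMIs lay inside the depth range of empty droplets. Most kept barcodes, 82.7%, 79.2% and 80.5%, fell in clusters with no class and were left out, and the reason was not tested. Doublets were sought per library with scrublet as built into scanpy, which marked few barcodes, so doublets were in effect not removed.

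Counts were scaled to 10000 per barcode and log-transformed. The 2000 most variable genes gave 30 principal components, and a graph of 15 neighbours was clustered with Leiden at resolution 1. Clusters were named by markers of 20 classes and written as AT2-like, club-like and so on, since each name is a hypothesis. A cluster led by cycling genes was left without a class. A class was compared when each library had at least 50 cells. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.

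UMIs were summed over the cells of a class in each library, and the control libraries were pooled by adding counts. The ratio of Kras mutant to control was taken between counts per total class UMIs, with exact 95% intervals for a ratio of Poisson counts. A count of 0 was set to a floor of 3 counts and gave a bound. After subtraction of free RNA every sum under the floor was set to it. Shares of cells have exact binomial (Clopper-Pearson) intervals. Without replicates no test was made between groups. A gene counted as past the rule of size when it had at least 50 UMIs over the libraries and a ratio of at least 2, or at most 0.5, against each control library. The genes named were those past the rule ranked by the bound of the ratio's interval nearest 1, 15 in each direction in AT2-like and club-like cells and 3 in the other classes, leaving out mitochondrial, ribosomal protein and haemoglobin genes and unnamed gene models. Named as well were up to 4 members of each list with most UMIs and up to 4 called members ranked in the same way. Kras, FGFP, the genes whose cell shares are given and genes in the closing section were named outside the rule.

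The 30 fixed gene lists were AT1, AT2 and club identity, the Krt8-high transitional and high-plasticity tumour states, MAPK feedback, S phase, G2 and M phase, p53, Hippo, Wnt and Notch, TGF beta, mesenchymal transition, distal progenitor and gut endoderm genes, polycomb, trithorax and histone acetylation regulators, MHC class I and II, interferon, chemokines, immediate early genes, unfolded protein response, glycolysis, oxidative phosphorylation, fatty acid synthesis, antioxidant enzymes, sex-linked transcripts and haemoglobins. The list of immediate early genes was fixed as immediate early and dissociation stress genes and includes heat shock genes. A member was measured with at least 20 UMIs and called higher or lower at a ratio of 1.5 against each control library with an interval that excluded 1. Each list median was set against 10000 random lists matched on expression in 10 bins. Free RNA was read from barcodes under 1000 UMIs in no class, which included shallow barcodes of clusters without a class, and its share per class and library was estimated from markers of other classes. Shares of cells were taken after thinning each cell to 1000 UMIs, and a cycling cell had at least 2 UMIs of the G2 and M phase list.

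These choices, apart from the barcodes used for free RNA and its estimated share, and most alternatives were fixed before the data were examined. Those fixed then were TMM and DESeq2 scaling, no gene minimum or 200 UMIs, a rule of size of 1.5, equal weights for the control libraries, leaving out either control library, 10% free RNA subtracted, equal numbers of cells at 1000 UMIs, a minimum of 1000 UMIs per cell, a mitochondrial share under 10%, doublets kept, Leiden resolutions of 0.5 and 2, thinning to 500 UMIs or none, and at least 3 UMIs of the cycling list. A minimum of 2000 UMIs, subtraction of the estimated free RNA and clustering without the genes past the rule were added after results had been seen.

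The comparison was tested on simulated data with 200 changed genes. In AT2-like cells it recovered 36% of genes set 2-fold higher, 16% of those set 2-fold lower, 88% of those set 3-fold higher and 68% of those set 3-fold lower. In club-like cells the same shares were 64%, 24%, 96% and 88%. The interval held the true fold for 93.5% of changed genes in AT2-like cells. The simulated counts were Poisson draws with the same rates for both control libraries. The real control libraries differed by more, with a chi-square per degree of freedom of 3.05 in AT2-like and 5.90 in club-like cells. The simulated values therefore cover counting error only and cannot show how the comparison performs with the spread between libraries.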

Results

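Single-cell RNA was measured by Drop-seq in lung cells of mice with a Kras mutation, labelled 6 weeks, and of control mice, after 4 doses of tamoxifen in each. Drop-seq tags transcripts at their 3' end in droplets and counts each molecule once by a unique molecular identifier (UMI). The series title names the question: the epigenetic basis of proliferation and plasticity of epithelial cells under oncogenic Kras. The Kras mutant group had 1 library; the labels give 2 such mice, handled separately, and do not say whether the library holds 1 animal. The control group had 2 libraries, Control 1 and Control 2, made after cells of 6 control mice had been pooled, so they were not separate animals. Immune cells were depleted with CD45 microbeads, and cells carrying the fluorescent reporter fGFP were enriched by a sort that let through other cells. Each library held 12000 barcodes. The total was 15489085 UMIs in Control 1, 17847210 in Control 2 and 15819246 in the Kras mutant library, with medians per barcode of 1002, 951 and 682. There were no replicates for a test between the groups, and every interval is a 95% interval that covers counting error only.

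Kras (chromosome 6, 145216699 to 145250239, GRCm38), the gene altered in the mutant mice, had 73 UMIs in Control 1, 134 in Control 2 and 1092 in the Kras mutant library among AT2-like cells, or 184, 141 and 182 counts per 1000000 UMIs (CPM). The ratio of Kras mutant to control was 1.18 (1.02 to 1.38) in AT2-like, 1.63 (1.34 to 1.98) in club-like, 1.44 (1.17 to 1.76) in ciliated-like and 1.36 (0.931 to 1.93) in endothelial-like cells. A 3' tag count gives the level of the gene and does not read the mutation. The FGFP reporter reached 463, 760 and 1112 CPM in AT2-like cells of Control 1, Control 2 and the Kras mutant library. It stood at 1373 CPM in Kras mutant barcodes under 1000 UMIs in no class, so these levels alone do not show how much came from the cells. After thinning to 1000 UMIs it was seen in 43.8% of control and 63.7% of Kras mutant AT2-like cells. The shares in endothelial-like cells were 28.7% and 27.5%.

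The first comparison asked which epithelial classes the libraries held. AT2-like cells, the surfactant-making class of the alveolus, were 86.2% (84.2 to 88.0) of the epithelial-like cells in the Kras mutant library and 16.9% (15.3 to 18.7) in the pooled controls. Club-like cells, the secretory class of the airway, were 6.99% (5.66 to 8.51) against 43.8% (41.6 to 46.1), and ciliated-like cells 6.84% (5.53 to 8.34) against 39.2% (37.0 to 41.5). The class numbers were 119, 204 and 1122 AT2-like cells in Control 1, Control 2 and the Kras mutant library, 467, 370 and 91 club-like cells, and 468, 281 and 89 ciliated-like cells. The AT2-like share was 11.3% in Control 1 and 23.9% in Control 2. Among the non-epithelial classes the same libraries held 376, 664 and 56 endothelial-like cells, 289, 363 and 17 fibroblast-like cells, 198, 180 and 4 macrophage or monocyte-like cells, and 50, 105 and 1 mast or basophil-like cells. When the genes past the rule of size were left out of the clustering, the AT2-like share was 89.8% in the Kras mutant library and 28.5% in the controls, and with a minimum of 2000 UMIs per cell it was 74.8% and 22.0%. The sort, the CD45 depletion and the minimum of 500 UMIs act on these shares, and median depths differed: 4652 UMIs in Kras mutant and 3618 in control AT2-like cells, 7428 and 1773 in club-like cells, and 6848 and 1235 in ciliated-like cells.

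**Figure D1:**
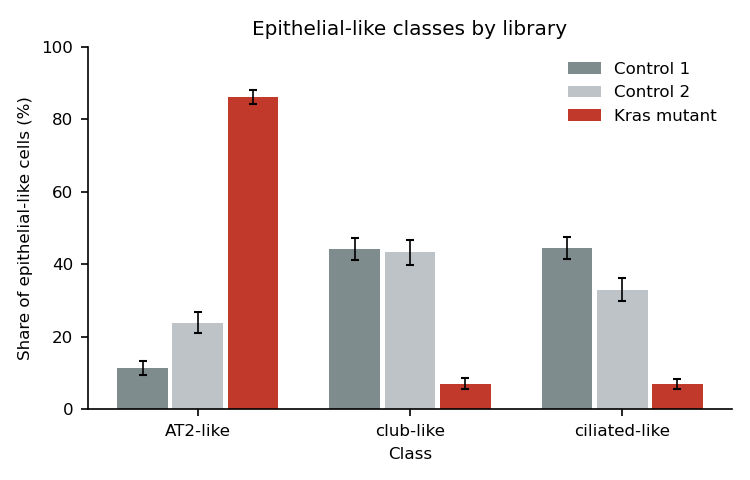
Share of epithelial-like cells in percent (vertical axis) by class (horizontal axis) for Control 1, Control 2 and the Kras mutant library, with exact 95% binomial intervals. The AT2-like bar is 86.2% in the Kras mutant library, 11.3% in Control 1 and 23.9% in Control 2.

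The second comparison set AT2-like cells of the Kras mutant library against those of the controls. The largest differences by the fixed ranking were in Meg3, an imprinted non-coding RNA (chromosome 12, 109541001 to 109571726), and Mthfd2, an enzyme of mitochondrial one-carbon metabolism. Meg3 had 3 and 4 UMIs in the control libraries and 4481 in the Kras mutant library, 144-fold higher (69.7 to 358). Mthfd2 had 0, 2 and 537 UMIs, 60.3-fold higher (16.6 to 499). Rian, a non-coding RNA of the same imprinted region (109603940 to 109661716), had 0, 1 and 189 UMIs, 42.4-fold higher (7.52 to 1684.7). Clu, which encodes the secreted chaperone clusterin, was 5.003-fold higher (4.46 to 5.63), and Lcn2, an iron-binding defence protein of inflamed epithelium (chromosome 2, 32384633 to 32388252), was 4.21-fold higher (3.86 to 4.59).

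Among the others of the 15 genes ranked highest, Gdf15, a stress-induced cytokine, was 15.9-fold higher (5.36 to 77.5), Trib3, a pseudokinase of the integrated stress response, 10.5-fold (4.75 to 28.8), and Gadd45a, a growth arrest gene, 4.83-fold (3.78 to 6.26). Atf5, a stress-response transcription factor, was 4.75-fold higher (3.81 to 5.99). Sprr1a, a cornified envelope protein, was 13.9-fold higher (6.33 to 38.2), Tnfsf9, a ligand of the TNF family, 7.50-fold (4.34 to 14.2), Slc26a4, an anion exchanger, 6.83-fold (4.85 to 9.91), and Lrg1, a secreted glycoprotein, 4.39-fold (3.90 to 4.96). H2-DMb2, a chaperone chain of MHC class II loading, had 0, 1 and 128 UMIs and was 28.7-fold higher (5.07 to 1143.8). Tenm4, a teneurin adhesion protein, had 0 UMIs in both control libraries and 139 in the Kras mutant library, and was at least 10.4-fold higher against a floor of 3 counts over the control group. Of these 15 genes, 14 lay above the free RNA of their own library, and 14 stayed past the rule of size after the estimated free RNA was removed, against 111 of all 205 genes past the rule. After the removal the controls were at or under the floor for Meg3, Mthfd2, Rian, Gdf15, H2-DMb2 and Tenm4. The same held for 15 of the 111 genes, so the size of these ratios after the removal was set by the floor.

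**Figure D2:**
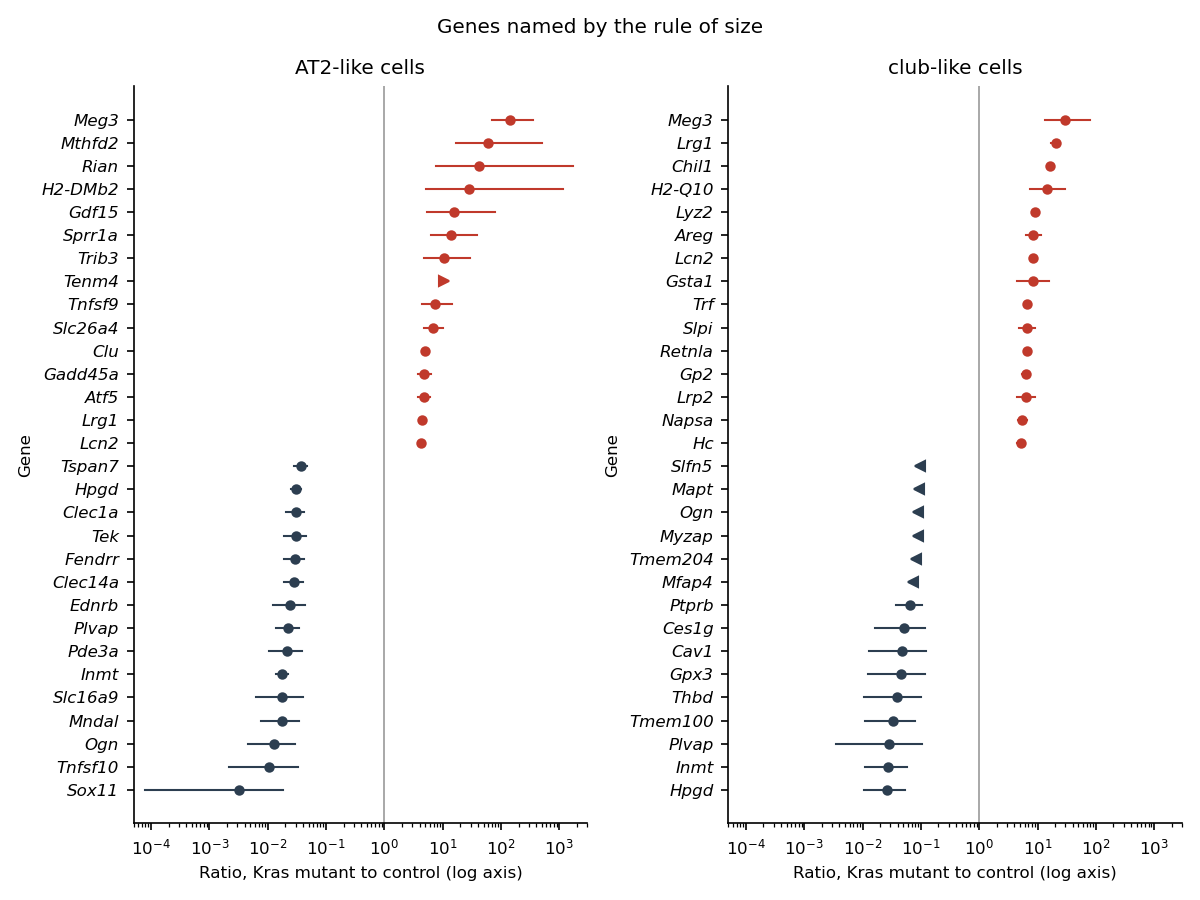
Ratio of Kras mutant to control (horizontal log axis) for the 15 genes ranked highest and the 15 ranked lowest by the rule in AT2-like and club-like cells, with points at the ratio and lines for 95% counting intervals; triangles are bounds where a group had 0 UMIs. Meg3 lies at 144 in AT2-like cells and 30.01 in club-like cells.

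Surfactant genes differed little in AT2-like cells. Sftpc, which encodes surfactant protein C (chromosome 14, 70520949 to 70524081), stood at a ratio of 1.22 (1.21 to 1.22), Sftpa1 at 1.25 and Sftpb at 1.28. After the estimated free RNA was removed these were 0.899, 0.973 and 1.00. Of the 24 measured genes of the AT2 identity list, 5 were higher, 2 lower and 17 neither, with a median log2 ratio of 0.22. After the removal 2 were higher and 3 lower, and the median turned to -0.19, below the central range of the random lists. The exceptions included Chil1, a chitinase-like protein (chromosome 1, 134182176 to 134190181), 3.12-fold higher (2.91 to 3.36), Ctsh, a cathepsin that processes surfactant, 2.19-fold higher, and Lyz1, a lysozyme, at 0.482 of the control level (0.458 to 0.508). Lyz2, the other lysozyme gene, was at 0.818.

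Gene lists linked to Kras signalling and to the injured alveolus lay high. Of 22 measured genes of the MAPK feedback and ERK target list, 9 were higher and 2 lower, with a median log2 ratio of 0.88, while 95% of random lists matched on expression lay from -0.29 to 0.25. Areg, an EGF receptor ligand, was 3.92-fold higher (3.11 to 5.01), Hbegf, another such ligand, 2.36-fold, Phlda1, an ERK-induced gene, 2.16-fold, and Ccnd1, which encodes cyclin D1, 1.84-fold. Ier3, an immediate early gene, was at 0.256, and Etv5, an ERK-regulated factor, at 0.862, which turned above 1 under TMM scaling. Of 26 measured genes of the Krt8-high transitional alveolar list, 14 were higher and 3 lower, with a median of 0.91. Krt8 (chromosome 15, 101996698 to 102004482) was 2.65-fold higher (2.27 to 3.11), its partner keratin Krt18 2.39-fold, Cdkn1a, a cell cycle inhibitor, 2.33-fold, and Tnfrsf12a, the TWEAK receptor, 3.74-fold. Krt8 itself stood at 346 CPM in Kras mutant AT2-like cells and at 424 in the free RNA of that library, and at the minimum of 2000 UMIs, where Sprr1a-high and AT1-like cells form their own clusters, the list median was 0.34, as it was 0.33 at a minimum of 1000 UMIs. The list lay higher still in ciliated-like cells, with a median of 1.28 and 18 of 23 genes higher, and at 0.29 in endothelial-like cells. Of 13 measured genes of the high-plasticity tumour list, 5 were higher and 3 lower, with a median of 0.48, against 1.03 in ciliated-like and 0.38 in endothelial-like cells. This median was 0.26 and 0.32 at minimums of 1000 and 2000 UMIs, within the random range of the main setting.

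All 7 measured genes of the MHC class II list were higher, with a median log2 ratio of 1.01. After removal of the estimated free RNA 4 were higher and the median was 0.71. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), was 2.17-fold higher (2.04 to 2.30), H2-Ab1 1.86-fold, H2-Eb1 1.93-fold and H2-Aa 1.65-fold. Of 22 measured genes of the unfolded protein response list, 9 were higher and 0 lower, with a median of 0.50; Hspa5, the main chaperone of the endoplasmic reticulum, was 1.77-fold higher, Herpud1, a factor of protein disposal there, 1.98-fold, and Ddit3, a stress transcription factor, 3.37-fold. In the glycolysis and hypoxia list 5 of 20 were higher and 0 lower, with a median of 0.34 that was 0.24 against Control 2 alone, within the random range, among them Hk2, a hexokinase, 2.23-fold and Gapdh 2.07-fold. In the chemokine and inflammation list 5 of 17 were higher and 3 lower, with a median of 0.65 that was 0.020 against Control 1 and 0.21 against Control 2 alone, and Icam1, an adhesion molecule, was 1.94-fold higher. Several of these lists were also high in the endothelial-like cells of the Kras mutant library, which lie outside the sorted lineage: the medians there were 2.20 for MHC class II, 0.77 for MAPK, 1.05 for glycolysis and 1.00 for chemokines, and 0.24 for the unfolded protein response.

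A cluster of 46, 28 and 24 barcodes in Control 1, Control 2 and the Kras mutant library, led by cycling genes and nearest to AT2 by its markers, was left without a class, so cell cycle values are those of the cells outside it. At the minimum of 2000 UMIs the order was the reverse, and a cluster led by cycling genes held 9, 18 and 39 cells. These were 0.844% (0.387 to 1.60), 1.22% (0.723 to 1.92) and 2.90% (2.07 to 3.94) of the kept barcodes. The number of cycling cells therefore had no settled direction across settings. The S phase list in AT2-like cells had a median log2 ratio of 0.41, or 0.11 at a minimum of 1000 UMIs, with 1 of 19 genes higher, Mcm7, and 1 lower, Mcm3, both subunits of the replicative helicase; after removal of the estimated free RNA 0 were higher and 2 lower. The G2 and M phase list had 0 of 12 genes higher or lower and a median of -0.08, which was 0.42 against Control 2 alone and positive under TMM and DESeq2 scaling. The p53 and senescence list had 3 of 21 higher and 3 lower, with a median of 0.27 that was 0.19 against Control 2 alone, within the random range, and -0.93 when equal numbers of cells were thinned to 1000 UMIs each. In the distal lung progenitor list 4 of 19 were higher and 4 lower, with a median of 0.18 that was -0.063 and -0.049 against Control 1 and Control 2 alone and -0.14 at a minimum of 1000 UMIs, and 0 were higher and 3 lower after removal of the estimated free RNA. In this list Myc, a growth regulator, had 0, 5 and 92 UMIs and was 4.13-fold higher (1.71 to 13.02). Of the haemoglobin transcripts, 3 of 4 were higher, with a median of 2.54; Hbb-bs had 4, 0 and 273 UMIs and was 15.3-fold higher (5.92 to 56.6). This did not hold across settings: the log2 ratio of Hbb-bs turned to -0.31 with doublets kept and was 0.28 at the minimum of 2000 UMIs. After removal of the estimated free RNA 1 of the 4 was higher, and all 4 were at or under the floor in the controls.

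Lower lists in AT2-like cells included interferon-response genes, with 12 of 19 lower and 0 higher and a median log2 ratio of -1.36. This median was -0.59 at the minimum of 2000 UMIs, within the random range of the main setting, -0.62 to 0.21. After removal of the estimated free RNA it was -0.91 with 8 lower, and controls were at or under the floor for 4 of 19 members. Ifitm3, which restricts virus entry, was at 0.166 (0.146 to 0.188) and Irf1, an interferon-induced factor, at 0.389. In the MHC class I list 3 of 11 were lower and 0 higher, with a median of -0.70 that was -0.14 against Control 1 alone and 0.13 at the minimum of 2000 UMIs, and 0 were lower after removal of the estimated free RNA; B2m, the light chain, was at 0.546. In the AT1 identity list 10 of 23 were lower and 2 higher, with a median of -0.47 that turned positive in 3 alternatives. The antioxidant list, with 16 of 28 lower and 2 higher, and the club identity list, with 16 of 28 lower and 2 higher, had medians of -1.22 and -0.99, which were 0.52 and 0.68 after removal of the estimated free RNA, where controls were at or under the floor for 7 of 25 and 5 of 14 members still measured; Cyp2f2, an airway cytochrome, was at 0.284 and Scgb3a2, a club-cell secretoglobin, at 0.305. The markers used to estimate the free RNA share of AT2-like cells included club markers. All of those belong to the club identity list and some also to the antioxidant list, so the medians after removal are not independent of the estimate. Endothelial-like cells had medians of -0.76 and -0.97 for these lists, against -0.04 for interferon response. Ciliated-like cells had -0.72 and -1.32. Their interferon median was -0.75, with 6 of 19 lower and 2 higher, and -0.064 after removal of the estimated free RNA.

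The chromatin lists bear on the epigenetic basis named in the series title. In the polycomb and DNA methylation list 0 of 24 were higher and 4 lower, with a median log2 ratio of -0.25, and Ezh1, a histone methyltransferase, was at 0.393 (0.286 to 0.543). In the trithorax and remodelling list 0 of 26 were higher and 1 lower, Smarca2, a remodelling ATPase, at 0.435 (0.395 to 0.479), with a median of -0.28, below the random range of -0.22 to 0.22, that was -0.15 and -0.19 against Control 1 and Control 2 alone and 0.010 when equal numbers of thinned cells were used. In the histone acetylation and demethylation list 0 of 27 were higher and 2 lower, Kat6a at 0.570 and Sirt1 at 0.591, an acetyltransferase and a deacetylase, with a median of -0.12 that was positive under TMM and DESeq2 scaling. The polycomb and histone acetylation medians lay within the random range. After removal of the estimated free RNA polycomb had 0 higher and 1 lower (-0.058). Trithorax then had 1 higher and 1 lower (-0.044), and histone acetylation 0 higher and 1 lower (0.067). Of the remaining lists, Wnt and Notch signalling had 5 of 17 lower and 0 higher, with a median of -0.51 that was -0.11 against Control 1 and -0.73 against Control 2 alone, and -0.21 with 2 lower after removal of the estimated free RNA. Hippo targets had 4 of 14 lower and 2 higher (-0.35, positive in 2 alternatives), TGF beta and matrix 3 of 23 in each direction (-0.12), and mesenchymal transition 5 of 13 lower and 1 higher (-0.07), of which the last pair of medians were positive under both scalings. Fatty acid and sterol synthesis had 2 of 24 higher and 3 lower (-0.18) and gut endoderm genes 1 of 10 lower and 0 higher (-0.08), medians that were also positive under both scalings; after removal of the estimated free RNA the synthesis list had 0 higher and 8 lower (-0.39). Oxidative phosphorylation had 2 of 26 higher and 0 lower (0.16) and sex-linked transcripts 2 of 5 lower and 0 higher (-0.44). The immediate early and dissociation stress list had 2 of 22 higher and 4 lower (0.13), but 9 higher and 1 lower after removal of the estimated free RNA (0.67). Its medians were -0.058 and 0.42 at minimums of 1000 and 2000 UMIs. Of the 30 lists, 10 lay above and 6 below the random range of the main setting, and 5 and 0 of these stayed there in every alternative and against each control alone. The 5 were MAPK, Krt8-high, MHC class II, unfolded protein response and haemoglobins, but the last list had no median in the settings where Hbb-bs fell most.

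Among the 15 genes ranked lowest in AT2-like cells, Sox11, a developmental transcription factor, had 16, 54 and 1 UMIs, a ratio of 0.00321 (8.01e-05 to 0.0185). Inmt, a methyltransferase of lung fibroblasts, was at 0.0176 (0.0136 to 0.0226), Plvap, a protein of endothelial diaphragms, at 0.0225, Tek, an endothelial receptor kinase, at 0.0299, Hpgd, which degrades prostaglandins, at 0.0310, and Tspan7 at 0.0368. Tnfsf10, Ogn, Mndal, Slc16a9, Pde3a, Ednrb, Clec14a, Fendrr and Clec1a lay from 0.0107 to 0.0300. In both control libraries all 15 stood below their level in the free RNA of the same library, and all 15 stayed past the rule of size after the estimated free RNA was removed. Only Hpgd, Tspan7, Ednrb, Clec14a and Clec1a then stood above the floor in Kras mutant cells. The ratios of the others after the removal were bounds set by the floor.

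By the rule of size, a ratio of at least 2 or at most 0.5 against each control library, 205 of 9400 genes were higher in AT2-like cells and 587 lower, so that 25.9% of the genes past the rule were higher; this share was 46.4% with TMM and 43.2% with DESeq2 scaling, which moved the median of all genes by 0.23 and 0.19 on the log2 scale. Between the control libraries, a comparison of 1 library with 1 other, 1124 genes differed as much. The like comparison of the Kras mutant library gave 980 higher and 944 lower against Control 1 alone. Against Control 2 alone it gave 437 higher and 914 lower. Counts simulated with no difference, and with counting error only, gave a mean of 928 between the control libraries. Between the groups they gave means of 21.8 higher and 3.30 lower. The 1124 left out genes with at most 3 UMIs in each control library and the 928 did not, so these counts are not matched. After removal of the estimated free RNA 111 of the 205 and 396 of the 587 stayed past the rule. Of the 111, 15 then had controls at or under the floor. Of the 396, 51 had Kras mutant cells and 5 had controls there. With 1 control library left out, also from the UMIs needed per gene, 422 of 9199 genes were higher against Control 2 and 932 of 8856 against Control 1; on the same 9400 genes these were 437 and 980. The AT2-like class was 1 cluster, but its cells separated by group under finer settings. At Leiden resolution 2 a cluster held 150, 209 and 21 cells of Control 1, Control 2 and the Kras mutant library and another 13, 21 and 1101. At a minimum of 2000 UMIs the clusters held 66, 124 and 2 cells, 1, 3 and 637 cells, and 0, 0 and 197 cells.

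**Figure D3:**
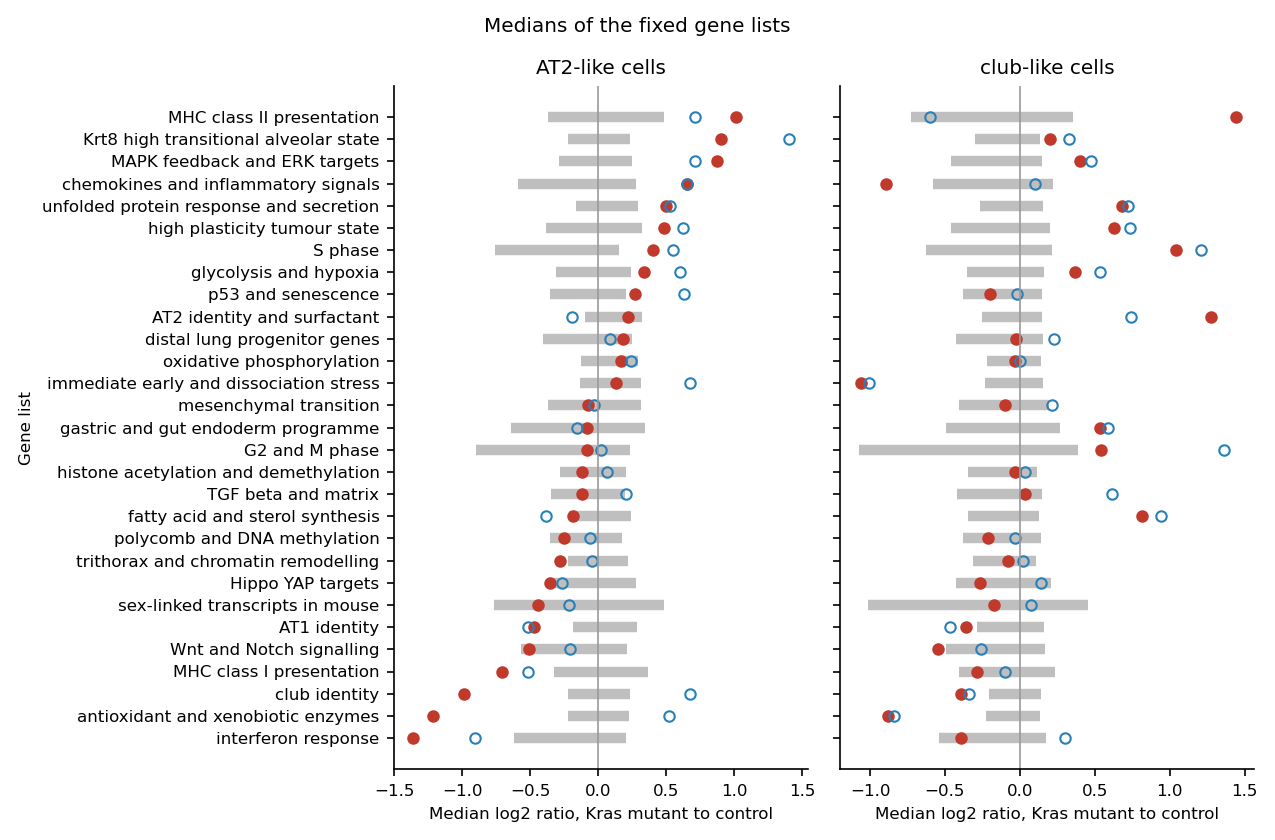
Median log2 ratio of Kras mutant to control (horizontal axis) of 29 fixed gene lists (vertical axis) in AT2-like and club-like cells, with filled points for the measured medians, open points after removal of the estimated free RNA and grey bars for the central 95% of random lists. The MHC class II list lies at 1.01 and 1.44; its open point in club-like cells rests on members at the floor.

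The third comparison set club-like cells of the Kras mutant library against the controls. Lrg1 (chromosome 17, 56119678 to 56122001) was 20.6-fold higher (17.4 to 24.7), Chil1 16.2-fold higher (14.8 to 17.8), and Lyz2, a lysozyme gene (chromosome 10, 117277331 to 117282321), 9.14-fold higher (8.76 to 9.54). Retnla, a secreted resistin-like protein (chromosome 16, 48842551 to 48844461), was 6.61-fold higher (6.49 to 6.74), Trf, which encodes transferrin, 6.71-fold (6.45 to 6.97), and Lcn2 8.41-fold (7.40 to 9.56). Areg was 8.41-fold higher (6.30 to 11.3), Slpi, a protease inhibitor of mucosal surfaces, 6.69-fold, Gp2, a glycoprotein that binds bacteria, 6.40-fold, and Gsta1, a glutathione transferase, 8.24-fold. Also named were H2-Q10, a class I-like gene, at 14.4-fold, Lrp2, an endocytic receptor, at 6.30-fold, Napsa, an aspartic protease that processes surfactant, at 5.48-fold, Hc, complement component C5, at 5.13-fold, and Meg3 at 30.01-fold (13.6 to 78.4). Of the 15, 14 stayed past the rule of size after the estimated free RNA was removed, the exception being Meg3, and 8 lay above the free RNA of their library.

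Of 24 measured AT2 identity genes, 17 were higher in club-like cells of the Kras mutant library and 0 lower, with a median log2 ratio of 1.28. Sftpc was 3.47-fold higher (3.40 to 3.54), Sftpa1 2.72-fold and Sftpb 2.43-fold. AT2 RNA was also abundant in shallow barcodes of that library. Sftpc stood at 109047 CPM in its barcodes under 1000 UMIs in no class, against 23268 in Control 1 and 14094 in Control 2. Of these 8781 Kras mutant barcodes 3968 came from a single cluster, and shallow AT2 cells among them were not excluded. The AT2 list was high in endothelial-like cells too, with a median of 1.11. After removal of the estimated free RNA 12 were higher and the list median in club-like cells was 0.74. For Sftpc the removal left nothing above the floor in Kras mutant club-like cells, so no ratio is given.

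**Figure D4:**
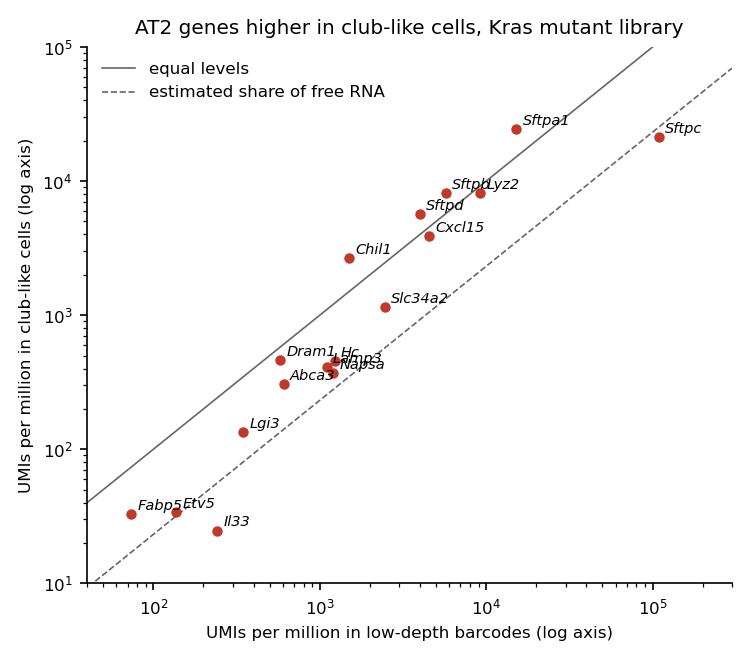
Level of the 17 AT2 identity genes higher in club-like cells of the Kras mutant library (vertical log axis, CPM) against their level in barcodes under 1000 UMIs in no class of that library (horizontal log axis), 1 point per gene. The solid line marks equal levels and the dashed line the estimated free RNA share of 23.2%; 4 genes lie above the solid line beyond their intervals.

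Cell cycle lists lay high in club-like cells. In the S phase list 9 of 15 were higher and 0 lower, with a median log2 ratio of 1.04. Hells, a remodeller of replicating chromatin, was 5.18-fold higher (3.25 to 8.32), Mcm5 4.75-fold (2.72 to 8.37) and Mcm3 (chromosome 1, 20802968 to 20820312) 3.28-fold (2.04 to 5.23), both helicase subunits. In the G2 and M phase list 4 of 9 were higher and 0 lower, with a median of 0.54, or 1 higher after removal of the estimated free RNA, among them Mki67, a proliferation antigen, 4.77-fold (2.46 to 9.32) and Top2a, a topoisomerase, 2.97-fold (1.81 to 4.82). Endothelial-like cells had medians of 0.23 and 0.32 for these lists.

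Synthesis and secretion lists were also high. Fatty acid and sterol synthesis had 13 of 25 genes higher and 1 lower, with a median of 0.82; Fasn, fatty acid synthase, was 4.07-fold higher and Scd1, a desaturase, 2.49-fold. The unfolded protein response list had 12 of 22 higher and 0 lower, with a median of 0.68, and Hspa5 was 2.41-fold higher, Sdf2l1 3.76-fold and Pdia6 2.14-fold, all chaperones or folding enzymes. The MAPK list had 8 of 21 higher and 3 lower, with a median of 0.40; Etv4, an ERK-regulated factor, had 0, 5 and 17 UMIs and was 14.005-fold higher (4.96 to 48.5). The Krt8-high list had 8 of 24 higher and 2 lower (median 0.20, or 0.057 with equal numbers of thinned cells), with Krt8 1.71-fold and Clu 3.58-fold higher. The high-plasticity list had 6 of 14 higher and 2 lower (0.63), glycolysis 5 of 19 higher and 0 lower (0.37), with Ldha, lactate dehydrogenase, 2.62-fold higher, and gut endoderm genes 4 of 10 higher and 0 lower (0.53), with the mucosal genes Tff2 2.29-fold and Muc5ac 2.92-fold higher. MHC class II had 4 of 6 higher and 0 lower (1.44), and removal of the estimated free RNA left 4 of the 5 members then measured at or under the floor in Kras mutant cells, so that no direction was left to read. Most of these lists were high in ciliated-like cells as well. Medians there were 0.84 for fatty acid and sterol synthesis, 0.44 for the unfolded protein response, 0.74 for MAPK and 1.28 for Krt8-high. They were 1.03 for high-plasticity, 0.63 for glycolysis, 0.41 for gut endoderm and 2.16 for MHC class II. Endothelial-like cells had 0.22, 0.24, 0.77, 0.29, 0.38, 1.05, -0.26 and 2.20 in the same order.

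Immediate early and dissociation stress genes were lower in club-like cells: 12 of 22 were lower and 1 higher, with a median log2 ratio of -1.06. Ciliated-like cells had a median of -0.37 for this list, with 8 of 22 lower and 2 higher, and endothelial-like cells -0.08. In club-like cells Fos was at 0.189 (0.162 to 0.219), Jun at 0.319, Egr1 at 0.363 and Zfp36, which destabilises mRNA, at 0.2403. In the antioxidant list 18 of 31 were lower and 2 higher (median -0.88), with Gsta2, a glutathione transferase, at 0.0820 (0.0221 to 0.213) and Aldh1a1, an aldehyde dehydrogenase, at 0.328. In the club identity list 9 of 28 were lower and 3 higher (-0.39); Cbr2, a carbonyl reductase, was at 0.416, Cyp2f2 at 0.440 and Scgb3a2 at 0.724, while Scgb3a1, another secretoglobin, was at 1.37. AT1 identity had 5 of 20 lower and 2 higher (-0.36), Wnt and Notch signalling 4 of 18 lower and 1 higher (-0.54, or -0.43 and -0.49 against each control alone, within the random range), and chemokines 6 of 14 lower and 5 higher (-0.89). The chemokine median was -0.75 against Control 1 on the same 14 genes, and 0.73 on the 9 still measured when Control 2 was left out; after removal of the estimated free RNA it was 0.10 with 0 lower.

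The other 12 lists lay within the range of random lists in club-like cells, and 10 of these medians turned sign in at least 1 alternative or against 1 control, so they give no direction. Interferon response had 3 of 18 lower and 0 higher (median -0.40), MHC class I 4 of 11 lower and 0 higher (-0.29), and p53 and senescence 3 of 21 lower and 0 higher (-0.20). Polycomb had 1 of 20 higher and 2 lower (-0.21), trithorax 2 of 26 lower and 0 higher (-0.08), and histone acetylation 2 of 26 higher and 0 lower (-0.03). TGF beta and matrix had 4 of 21 higher and 1 lower (0.03), mesenchymal transition 3 of 15 higher and 4 lower (-0.10), and Hippo targets 1 of 13 higher and 2 lower (-0.27). Distal progenitor genes had 4 of 18 in each direction (-0.02), oxidative phosphorylation 1 of 26 lower and 0 higher (-0.03) and sex-linked transcripts 1 of 5 lower and 0 higher (-0.17). After removal of the estimated free RNA TGF beta and interferon response had 0.62 and 0.30. Of 11 lists above and 6 below the random range of the main setting in club-like cells, 9 and 2 stayed there in every alternative and against each control alone.

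Of the 15 genes ranked lowest in club-like cells, 7 stayed past the rule of size after the estimated free RNA was removed. Of the 15 only Ces1g then stood above the floor in Kras mutant cells, so the other ratios after the removal were set by the floor. In both control libraries 14 stood below the free RNA, among them Hpgd at 0.0261 (0.0105 to 0.0539), Inmt at 0.0276, Plvap at 0.0290, Tmem100 at 0.0336, Thbd at 0.0389, Gpx3 at 0.0459, Cav1 at 0.0473 and Ptprb at 0.0648. The exception was Ces1g, a carboxylesterase, at 0.0506 (0.0163 to 0.119). Mfap4, Tmem204, Myzap, Ogn, Mapt and Slfn5 had 0 UMIs in the Kras mutant cells and were at least 13.4, 12.3, 11.2, 11.2, 10.8 and 10.4-fold lower against a floor of 3 counts.

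By the rule of size 137 of 8384 genes were higher in club-like cells and 656 lower, and 202 differed as much between the control libraries. Counts simulated with no difference, and with counting error only, gave means of 4.95, 47.3 and 48.1. On the same genes 856 were lower against Control 1 alone, and 406 of the 5721 that met the minimum without Control 2. The class joined a pair of clusters, with 158, 208 and 62 cells in one and 309, 162 and 29 in the other in Control 1, Control 2 and the Kras mutant library. At a minimum of 2000 UMIs its cells separated more by group, into clusters of 127, 188 and 4, of 39, 65 and 13, and of 2, 1 and 87 cells. AT2-like and club-like cells shared 27 genes higher and 269 lower, where independent draws would share 1.98 and 33.5. Other lineages shared genes as well: AT2-like and ciliated-like cells 24 and 247 (2.11 and 30.3), and AT2-like and endothelial-like cells 20 and 129 (2.23 and 61.2). All used the same libraries and their free RNA, so the draws are not independent.

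Shares of cells with a UMI were compared after thinning every cell to 1000 UMIs, which kept 313 of 323 control and 1098 of 1122 Kras mutant AT2-like cells, and 847 of 1040 and 40 of 56 endothelial-like cells. The cluster led by cycling genes lies outside the class, so a cycling share counts only cells left in it. Cells with at least 2 UMIs of the G2 and M phase list were 5.11% (2.95 to 8.17) of control and 2.28% (1.48 to 3.34) of Kras mutant AT2-like cells, and without thinning 22.9% and 27.5%. Krt8 was seen in 11.2% (7.91 to 15.2) of control and 20.4% (18.1 to 22.9) of Kras mutant AT2-like cells, without thinning in 31.3% and 57.1%. In endothelial-like cells, which lack Krt8, it was seen in 7.20% and 12.5% (4.19 to 26.8), so the Kras mutant share lay within the interval of this background. Ager, an AT1 gene, was seen in 61.0% and 74.2% of AT2-like cells, without thinning in 85.4% and 95.7%, against 15.3% and 22.5% of endothelial-like cells. Median depths were 3618 and 4652 UMIs in AT2-like and 1777 and 1436 in endothelial-like cells.

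Scgb1a1, Scgb3a2 and Hopx in AT2-like cells and Sftpc and Hopx in club-like cells lay at or below the endothelial-like background in both groups. In AT2-like cells Scgb1a1, a club-cell secretoglobin, was seen in 6.07% and 4.64%, against 7.08% and 7.50% of endothelial-like cells, and without thinning in 19.8% and 15.6%. Scgb3a2 was seen in 84.0% and 54.6%, against 90.9% and 70.0%, and without thinning in 99.1% and 94.0%. Hopx, an AT1 gene, was seen in 19.8% and 10.6%, against 39.2% and 17.5%, and without thinning in 48.0% and 29.9%. Its level in control AT2-like cells, 438 CPM, lay above the 377 CPM of the control free RNA, so the shares do not show that Hopx there was background only. Among club-like cells, where 585 of 837 control and 91 of 91 Kras mutant cells could be thinned, Sftpc was seen in 84.3% and 100%, against 91.9% and 100% of endothelial-like cells, and without thinning in 98.9% and 100%. Hopx was seen in 27.9% and 8.79% of club-like cells, without thinning in 52.8% and 54.9%. Krt8 lay above the background in club-like cells, in 29.7% and 34.1%, without thinning 52.6% and 85.7%. Ager was seen in 24.96% and 36.3%, without thinning 40.02% and 72.5%, and its control share, with an interval of 21.5 to 28.7, lay above the background of 15.3%, while its Kras mutant share lay within the interval of the background, 22.5% (10.8 to 38.5).

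The remaining classes were compared to show what differed between the libraries whatever the class. In ciliated-like cells Sncg, which encodes gamma-synuclein, was 34.3-fold higher (23.8 to 51.0), Prss22, an airway serine protease, 27.3-fold (14.95 to 54.7) and Meg3 34.4-fold (14.9 to 97.3), while Inmt was at 0.00536, Tspan7 at 0.00646 and Clec14a, at 0 UMIs in the Kras mutant cells, at least 33.2-fold lower. In endothelial-like cells Ankrd37, a hypoxia-induced gene, was 18.8-fold higher (11.9 to 29.7), Ntrk2, a neurotrophin receptor, 17.0-fold (11.4 to 25.4) and Cd74 10.7-fold (8.75 to 13.1), while Gsn, which encodes gelsolin, was at 0.0570, Inmt at 0.0863 and Slc16a9, at 0 UMIs, at least 10.2-fold lower. By the rule of size 192 genes were higher and 543 lower of 8237 in ciliated-like cells, and 267 higher and 910 lower of 7384 in endothelial-like cells. Simulated counts with no difference and counting error only, at the same depths, gave means of 96.3 higher and 467 lower in endothelial-like cells, and 3.60 and 33.1 in ciliated-like cells.

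Mitochondrial transcripts made up 8.75%, 5.70% and 4.98% of the UMIs of AT2-like cells in Control 1, Control 2 and the Kras mutant library, and ribosomal protein transcripts 3.27%, 3.85% and 5.06%. The estimated share of free RNA in AT2-like cells was 40.7%, 34.8% and 25.6% in the same order, and in club-like cells 29.6%, 18.9% and 23.2%.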

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

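Each of the tests in this part was chosen only after the result was seen, and the Kras mutant group had 1 library, so the genotype cannot be separated from the library.

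In AT2-like cells 205 genes were past the rule of size on the higher side, among them Meg3 and Lcn2. A smaller part of control UMIs coming from AT2 cells would raise AT2 genes alike by at least 2-fold, but the upper bound of the ratio lay under 2 for 21 of the 24 measured AT2 identity genes, a list not chosen by its ratios. Free RNA of the Kras mutant library is not the whole source for the 149 genes that lay above it, whereas the other 56 had a median of class level over free RNA of 0.948, which leaves open whether their RNA came from the cells, and of all 205 genes 111 stayed past the rule after the estimated free RNA was subtracted. Of these 111 genes, 15 had controls at or under the floor after the subtraction. AT1-like and Sprr1a-high cells counted in the class would lose the difference at the minimum of 2000 UMIs, where the median log2 ratio was 1.59 against 1.58 and 85.1% of 202 measured genes kept a pooled ratio of at least 2, although only 111 of the 205, the same number, stayed past the rule against each control library, 26 having too few UMIs and 68 a smaller ratio to a control library. A difference between Kras mutant and control AT2 cells may remain as a hypothesis for the 149 genes, untested with 1 library.

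In AT2-like cells 587 genes were lower. For 539 of them the control class lay not above the control free RNA, at a median of 0.611 of it; the free RNA of these genes differed between the groups about as the class did, by a median log2 ratio of -2.19 against -2.05, but 0.611 lies above the estimated free RNA share of 36.6%, and 348 of the 539 stayed past the rule after subtraction, so free RNA and expression cannot be told apart for them because the estimate is a single share for all genes. Of the 348 genes, 51 had Kras mutant cells and 5 had controls at or under the floor after the subtraction. For the 48 genes outside the 539, such as Lyz1 and Acot7, the control class lay above the free RNA, which argues against free RNA as their source. Droplets of mixed AT2 and endothelial RNA would leave at the minimum of 2000 UMIs, where the median log2 ratio was -1.69 against -1.87 and 84.3% of 548 measured genes kept a pooled ratio of at most 0.5, although only 226 of the 587 stayed past the rule, 254 having too few UMIs and 107 a smaller difference from a control library. What stays open for the 48 genes, and with free RNA for the 539, is a difference between the groups, which was not tested.

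In club-like cells 17 AT2 identity genes were higher in the Kras mutant library. Free RNA of AT2 cells does not account for 4 of them, Sftpa1, Sftpb, Sftpd and Chil1, which lay above it, while the other 13 had a median of 0.388 of the free RNA level against an estimated share of 23.2%, and for these free RNA and expression cannot be told apart because the estimate is a single share for all genes. Droplets that hold a club and an AT2 cell would supply at most 13.3% of the UMIs by the level of Sftpc, and 10 genes lay above that limit, Chil1 by 9.70-fold and Sftpa1 by 5.09-fold. The other 7, Sftpc, Napsa, Abca3, Etv5, Lgi3, Il33 and Fabp5, did not lie above the limit beyond error, so joined droplets and expression cannot be told apart for them because Sftpc sets the limit. Of the 4 genes, Sftpa1, Sftpb and Sftpd already stood at 9021, 3336 and 2939 CPM in control club-like cells. Their higher level therefore need not mean AT2 genes newly taken on. A higher level in club cells may be a hypothesis for the 4 genes, with no second Kras mutant library to test it.

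Acot7, an acyl-CoA thioesterase, was at 0.464 (0.416 to 0.518) in AT2-like cells and 3.97-fold higher (3.24 to 4.87) in club-like cells, and the difference between the classes was not tested. Mcm3, a helicase subunit, was at 0.417 (0.259 to 0.686) in AT2-like cells and 3.28-fold higher (2.04 to 5.23) in club-like cells, again not tested. These were the 2 genes past the rule as lower in AT2-like and higher in club-like cells, where independent draws would give 7.62. In AT2-like cells Mcm3 stood at 17.6 and 22.1 CPM in the control libraries, against 17.3 in the control free RNA. In the Kras mutant library it stood at 8.66 CPM, against 12.6 in the free RNA. Its lower level in AT2-like cells was therefore not shown to be expression of the cells.

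In barcodes under 1000 UMIs in no class, Sftpc stood at 109047 CPM in the Kras mutant library, 23268 in Control 1 and 14094 in Control 2. The reporter FGFP stood at 1373 CPM in these barcodes of the Kras mutant library.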

How the results depend on the processing

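A minimum of 2000 UMIs, subtraction of the estimated free RNA and clustering without the genes past the rule of size were chosen after results had been seen; the other alternatives were planned. The cause of a difference between settings was not tested. No paired analysis was possible because the groups share only the replicate number 1, which pairs no animals, and no test was made.

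Clustering and cell filters acted on AT2-like results. The AT2-like share of epithelial-like cells in the controls was 21.3% with doublets kept, 26.1% and 20.8% at Leiden resolutions 0.5 and 2, 26.6% at a minimum of 1000 UMIs, 2.25% with a mitochondrial share under 10%, 22.0% at a minimum of 2000 UMIs and 28.5% when clustered without the genes past the rule of size. In the Kras mutant library it was 84.0% with the mitochondrial share under 10%, 74.8% at 2000 UMIs and 89.8% without those genes. The share of the Kras mutant library stayed above that of the controls in each. The number of genes lower in AT2-like cells was 385 with doublets kept and 283 at 2000 UMIs. Keeping doublets put back only 2, 1 and 0 barcodes of Control 1, Control 2 and the Kras mutant library. These are too few to supply the differences of that setting themselves, which came with a new clustering. The AT1 identity median was 0.062 with doublets kept, 0.13 at Leiden resolution 0.5 and 0.34 at resolution 2. With doublets kept Hbb-bs had a log2 ratio of -0.31. At resolution 2 Igfbp2 had 1.68 and Spock2 0.48, and at 2000 UMIs Igfbp2 had 0.94 and the MHC class I median was 0.13. With a mitochondrial share under 10% AT2-like genes gave no value, since Control 1 had 4, Control 2 had 20 and the Kras mutant library 984 cells, and each library needed at least 20; there a cluster nearest to AT2 with 88, 164 and 23 barcodes was left without a class for its top genes, which lowers the share of 2.25%.

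Scaling and gene rules acted on the counts of genes. In AT2-like cells 391 genes were higher with TMM and 358 with DESeq2 scaling. Without a gene minimum 2821 were lower and 1804 differed between the control libraries; with a minimum of 200 UMIs 112 were higher, 179 lower and 219 differed between controls; with a rule of size of 1.5 these were 698, 1160 and 2845. In club-like cells 707 were higher, 1281 lower and 1646 different between controls without a minimum, 55, 148 and 13 with a minimum of 200 UMIs, and 463, 1261 and 1045 with a rule of size of 1.5. Leaving out 1 control library also took its UMIs from the minimum per gene, so fewer genes were counted. It gave 422 to 932 genes higher in AT2-like cells, and in club-like cells 406 to 573 genes lower, of 5721 and 7138 counted, and a chemokine median from -0.66 to 0.73, over 13 and 9 measured genes; on the main genes 856 and 857 were lower and the medians were -0.75 and -0.84.

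Depth limits what can be seen. With the same number of cells at 1000 UMIs each, 23 genes were higher and 64 lower in AT2-like cells and 56 differed between controls, and in club-like cells 29, 40 and 29. In AT2-like cells the MHC class I median was then 0.16, p53 and senescence -0.93 and trithorax 0.010, and in club-like cells chemokines had 0.73 and Sparc -0.22. The cycling share of AT2-like cells was 0.624% in the Kras mutant library and 0.929% in the controls when thinned to 500 UMIs, 27.5% and 22.9% with no thinning, and 0.364% and 0.639% with at least 3 UMIs.

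Subtraction of the estimated free RNA gave 2062 genes different between controls in AT2-like and 785 in club-like cells, where 220 genes were higher. In AT2-like cells the antioxidant median was 0.52, club identity 0.68, Fn1 0.19 and Notch1 0.12. The antioxidant and club identity lists hold club markers from which the free RNA share was estimated. In club-like cells chemokines had 0.10. Other values rest on a side where the subtraction left nothing above the floor of 3 counts, so they are set by the floor and show no direction: Cyp2f2 at 5.02 in the controls of AT2-like cells, and in Kras mutant club-like cells Sftpc at -9.07, H2-Aa at -0.60, H2-Ab1 at -1.03, Zeb2 at 1.16 and the MHC class II median at -0.60. With 10% free RNA subtracted 520 genes differed between controls in club-like cells and Il33 had -0.23. The MAPK and Krt8-high medians in AT2-like cells were 0.71 and 1.40 with the estimated free RNA subtracted, and 0.72 and 0.33 at a minimum of 1000 UMIs.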

Other observations

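At the minimum of 2000 UMIs, a setting chosen after the main result was seen, a cluster with AT1 markers stood apart from the AT2-like cells. It held 98 cells of the Kras mutant library, 7.28% (5.95 to 8.80) of its kept barcodes, beside 9 cells of Control 1 and 8 of Control 2. Ager, Hopx, Aqp5 and Rtkn2, all AT1 genes, stood at 3511, 693, 702 and 141 CPM in the 98 Kras mutant cells and at 1071, 139, 288 and 12.7 CPM in the free RNA of that library. The size of the cluster was not compared with the controls, because some genes that mark it differed between the libraries, and the sort acts on the number.

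Some genes lower in AT2-like cells of the Kras mutant library stood above the free RNA in the controls, and the examples were chosen after the values were seen. Lyz1 was at 0.482 (0.458 to 0.508), Apoe, which encodes a lipid carrier, at 0.343 (0.300 to 0.393), Cst8, a cystatin, at 0.341 (0.275 to 0.424), Anpep, a membrane aminopeptidase, at 0.351 (0.270 to 0.456) and Snhg11, a non-coding RNA, at 0.450 (0.393 to 0.517).

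Haemoglobin transcripts made up 0.332% of the UMIs of endothelial-like cells in the Kras mutant library, against 0.00105% in Control 1 and 0.000363% in Control 2. All 4 measured haemoglobins were higher there, with a median log2 ratio of 9.43.

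Igha, the immunoglobulin A heavy chain of plasma cells, stood at 122 CPM in the barcodes under 1000 UMIs in no class of Control 1, 2.41 in Control 2 and 2.28 in the Kras mutant library. Of its 503 UMIs there 445 came from 348 barcodes of a cluster led by immunoglobulin genes, and without them the level was 15.1 CPM. That cluster held 872, 16 and 0 barcodes of the libraries and had no class in the main setting, but was named plasma at Leiden resolutions 0.5 and 2. These barcodes were counted as free RNA, so the level does not show that Igha was free.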
